A study of Paenibacillus amylolyticus
Microbacterium oxydans
Stenotrophomonas rhizophila
Xanthomonas retroflexus and Xanthomonas retroflexus and Stenotrophomonas rhizophila
Xanthomonas retroflexus with 17 samples.

How the data were processed

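RNA was sequenced from biofilms of Xanthomonas retroflexus grown alone or with other bacteria, in 17 libraries of 5 groups. The labels give 3 libraries of the single-species biofilm, 3 each of the dual-species biofilms with Stenotrophomonas rhizophila, Microbacterium oxydans or Paenibacillus amylolyticus, and 5 of the biofilm of all 4 species. Per the labels' protocols, cultures were adjusted to an optical density of 0.15 at 600 nm in tryptic soy broth, grown for 24 h at 24 °C in polystyrene wells, rinsed free of planktonic cells, scraped off and stored in RNAlater. Cells were then opened with lysozyme and bead beating, RNA was purified on columns and DNA was digested. The submitters' processing notes name CASAVA 1.8.2 and Bowtie2 2.0.5 with no role; mapping settings and the counting step are not given in the sources used here. Nothing in the labels says whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

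The authors deposited 1 table with a whole number for each of 17388 predicted genes in each library, not scaled between libraries. These values are a coverage signal (bases covered, summed over a gene) and not numbers of reads. Of the X. retroflexus values between 1 and 138, 78.7% lay in 41 to 46, 82 to 92 or 123 to 138, the sums that 1, 2 and 3 short reads would give, although these intervals hold 23.9% of the whole numbers in that range. All values were divided by 44, the median of the values from 36 to 50, and are called read equivalents. A second deposited table gives each gene's contig, start, end and strand; positions are given here counted from 1 on the authors' assemblies. The files do not pair gene identifiers with names or products, and no genome sequence or annotation was used here, so functional gene lists fixed before the data were examined could not be applied, and genes are given by identifier and position.

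Each gene was given to a species by the prefix of its identifier, which carries the same digit as the species' code in the sample labels. This gave 4202 genes on 91 contigs for X. retroflexus, 3800 for S. rhizophila, 3796 for M. oxydans and 5576 for P. amylolyticus. A rule based on signal per contig, with a contig given to X. retroflexus where its single-species mean was at least a fraction of 0.2 of the highest group mean, placed all 4205 genes with the X. retroflexus prefix there, together with 866 S. rhizophila, 3 M. oxydans and 22 P. amylolyticus genes. It placed 5559 P. amylolyticus genes with their own species, but only 74 S. rhizophila and 9 M. oxydans genes. It left 2806 S. rhizophila and 3787 M. oxydans genes unassigned, so it does not check the prefixes of these species. In 3 of the assemblies a contig of the same recorded length, 5386, held 14 genes in all, with genes of 1542 and 987 bases in each. These contigs were left out of totals and tests, a choice made after seeing the data, because length and gene sizes match the phage commonly added as a sequencing control.

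A count model had been planned, but the values are not read counts, so the tests were run with limma 3.58.1 in R 4.3.3. X. retroflexus genes were kept where at least 3 libraries reached the level of 10 read equivalents in the library of median size (2570 genes), and library sizes were the X. retroflexus totals scaled by trimmed means of M values (30% of ratios and 5% of levels trimmed at each end), computed by own code. Values were modelled with voomWithQualityWeights, 1 weight per group, a prior of 0.5 read equivalents and robust empirical Bayes over all 17 libraries, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. This form of the model was not fixed before the data were seen. Weights per group were favoured because replicate spread differed between groups (median SD of log2 values 0.297 in the 4-species group and 0.677 to 1.23 in the others). Fits without weights, with a weight per library, with the second scaling and with the strictest filter were run beside it, and their numbers of called genes had been seen when it was adopted; all are among the alternatives. Levels are in CPM, here read equivalents relative to the scaled X. retroflexus library size, as mean ± SD, and log2 fold changes have their standard error (SE). The same model was fitted to P. amylolyticus genes in the libraries of its dual-species and 4-species biofilms (2948 genes). S. rhizophila and M. oxydans genes were not tested, since libraries lacked the 50000 read equivalents set beforehand as a minimum. Runs of 5 or more tested genes on 1 strand with gaps under 50 bp (17 runs, 111 genes) were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Sets of genes by contig were also tried and are not reported. Species shares were compared by exact two-sided permutation tests, 9 in the family.

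Named genes followed a rule fixed beforehand: of the called genes with an absolute log2 fold change of at least 1 and no overlap between the replicates of both groups, the 2 that rose and the 2 that fell with the smallest p in each comparison, 1 each for P. amylolyticus, and up to 3 runs. Genes named in 1 comparison are also given in others, so 5 are given below the sum of dual responses. Totals ranged from 3.40 to 38.5 Mb, or 77255 to 875587 read equivalents, and X. retroflexus read equivalents from 69704 to 389470 per library. Intervals of shares in single libraries are 95% Wilson intervals on read equivalents and, like the floor of 3 reads used for a level of 0, cover counting error only. No 2 replicates agreed within sampling noise: chi-square per degree of freedom between replicates ranged from 1.81 to 47.6. On simulated data drawn from the real means and spreads (2028 genes tested), 34.2% of genes with a 4-fold change were recovered for the dual with S. rhizophila, 45.2% for that with M. oxydans, 72.6% for that with P. amylolyticus and 90.4% for the 4-species biofilm, each against single. For 2-fold changes the shares were 3.61%, 6.02%, 13.3% and 33.7%. In the P. amylolyticus test (2840 simulated genes tested) 41.1% of 2-fold and 100% of 4-fold changes were recovered. Alternatives covered scaling, filters, weights, pseudocount, depth, the species rule, a replicate block and leaving out each library.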

Results

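The data are bacterial RNA-seq profiles of biofilms, the surface-attached communities left in a well after the liquid and loose cells are removed. Xanthomonas retroflexus was grown alone (single, n = 3), with 1 partner (dual with S. rhizophila, M. oxydans or P. amylolyticus, n = 3 each) or with all 3 partners (4-species, n = 5). The series asks how X. retroflexus gene expression differs in a multispecies biofilm described as synergistic. The libraries held 3.40 to 38.5 Mb of coverage summed over genes, and X. retroflexus genes held 69704 to 389470 read equivalents per library. Mean totals were 4.16 ± 0.727 Mb in single (SD, n = 3), 8.86 ± 5.17 in dual S. rhizophila, 5.04 ± 1.47 in dual M. oxydans, 25.4 ± 5.00 in dual P. amylolyticus and 24.3 ± 8.67 in the 4-species group.

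P. amylolyticus supplied much of the RNA wherever it was added. Its genes held 68.5 ± 12.6% of the coverage in its dual biofilm (SD, n = 3) and 52.2 ± 4.83% in the 4-species biofilm (n = 5), and X. retroflexus genes held 30.9 ± 12.4% and 44.5 ± 4.88%. In the duals with S. rhizophila and M. oxydans, X. retroflexus genes held 92.2 ± 5.71% and 94.7 ± 6.02%. S. rhizophila genes held 3.22 ± 0.405% of the coverage in the 4-species biofilm and 7.60 ± 5.93% in its dual, and M. oxydans genes 0.0233 ± 0.00663% and 0.379 ± 0.331%. No difference passed correction over the 9 share comparisons by exact two-sided permutation tests: adjusted p ranged from 0.161 to 1. These group sizes did not allow any difference to pass, however large, so this outcome cannot decide whether shares differ. X. retroflexus shares in the 4-species group lay below every library of the duals with S. rhizophila and M. oxydans (exact p = 0.0357 each before correction, the smallest that 5 against 3 can give), whereas 3 against 3 cannot go below 0.1. The single libraries, to which no partner was added, held 1.17 to 1.41% S. rhizophila and 0.869 to 1.11% P. amylolyticus coverage. They are not the lowest level for P. amylolyticus, whose genes held 0.00877 to 0.0779% in the libraries labelled dual S. rhizophila and dual M. oxydans. M. oxydans genes held 0 in the single libraries, which at these depths allows shares up to 0.00379%.

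**Figure D1:**
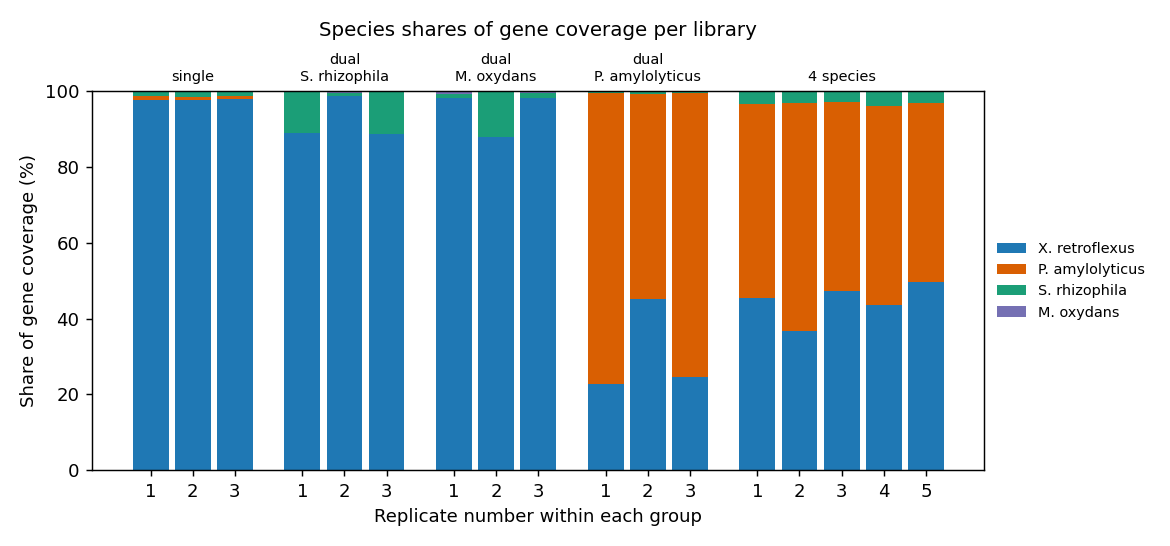
Share of gene coverage (%) of each species (colours) in each of the 17 libraries, with replicate numbers on the horizontal axis and groups as labelled above. P. amylolyticus holds 47.3 to 60.1% in the 4-species libraries, and replicate 2 of the duals labelled S. rhizophila and M. oxydans departs from the other replicates of its group.

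The partner RNA went against the label in 2 libraries. The library labelled dual S. rhizophila 2 held 0.754% S. rhizophila coverage (95% Wilson interval 0.724 to 0.784%), below the single libraries, and 0.434% M. oxydans coverage (0.412 to 0.457%). The library labelled dual M. oxydans 2 held 12.2% S. rhizophila coverage (12.0 to 12.4%) in 1081 genes and 0.00216% M. oxydans coverage (0.000664 to 0.00705%). The other libraries labelled dual S. rhizophila held 10.9 and 11.2% S. rhizophila, and the others labelled dual M. oxydans 0.511 and 0.623% M. oxydans. Groups follow the labels throughout, so each of these duals includes 1 library whose partner RNA does not match its label.

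In the dual biofilm with S. rhizophila, 3 of 2570 X. retroflexus genes rose against single and 0 fell (limma, adjusted p under 0.05), with 226 at an unadjusted p under 0.05. S300001633, on contig 45 at 27623 to 28225 (plus strand), was 21.1-fold higher: 1299 ± 806 against 49.9 ± 14.3 CPM (SD, n = 3 each), a log2 fold change of 4.40 ± 0.79 (SE) with adjusted p = 0.00240. S300001699, on contig 47 at 2642 to 4210 (plus strand), was 14.6-fold higher, at 2169 ± 769 against 147 ± 74.4 CPM (log2 3.87 ± 0.70, adjusted p = 0.00240). The third gene, on contig 20 at 65644 to 65892 (minus strand) and named after its values were seen, was 4.10-fold higher, at 89877 ± 57151 against 18170 ± 5034 CPM (adjusted p = 0.0391). A run of 5 genes on contig 16 at 71778 to 77637 fell, with a mean log2 fold change of -2.29 and adjusted p = 0.00786 (camera; 0 of 5 members called lower), and the call was lost with an estimated correlation (adjusted p = 0.127). Without single 2 or without single 3 the count was 0, and without dual S. rhizophila 3 it was 24. Without group weights it was 38, of which 23 fell. The run count was 0 without dual S. rhizophila 3 and 2 without the library labelled dual S. rhizophila 2.

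In the dual biofilm with M. oxydans the same 2 genes, S300001699 and S300001633, were the genes that rose against single, and 0 fell, with 177 genes at an unadjusted p under 0.05 (limma). S300001699 was 12.2-fold higher, at 1853 ± 601 CPM (n = 3; log2 3.61 ± 0.65, adjusted p = 0.00524). S300001633 was 11.6-fold higher, at 691 ± 323 CPM (log2 3.53 ± 0.76, adjusted p = 0.0460). The run on contig 16 at 71778 to 77637 fell by a mean log2 of -1.41 (camera, adjusted p = 0.0209; 0 of 5 members called lower), a call lost with an estimated correlation (adjusted p = 0.20; 0.00858 to 0.224 over its alternatives) and without single 1, single 3 or any library of this dual, each of which gave 0 runs. The count was 1 without single 1 or dual M. oxydans 3 and 0 without single 2. Without single 3 neither gene was called, and the 1 gene called was another. S300001699 kept its call in 15 of 17 alternatives, with adjusted p up to 0.170. S300001633 kept its direction in all 18 alternatives in which it was tested and passed the threshold in 7, with adjusted p from 0.0103 to 0.493.

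The responses differed among the 3 duals for 125 genes (limma, adjusted p under 0.05; 506 at an unadjusted p under 0.05). For 102 of these the dual with P. amylolyticus was the group farthest from the others, lower for 78 genes and higher for 24. Tested directly, P. amylolyticus against S. rhizophila duals differed at 170 genes and P. amylolyticus against M. oxydans duals at 186, while M. oxydans against S. rhizophila duals differed at 0 genes (175 at an unadjusted p under 0.05). Each of the groups in this last comparison includes 1 library with the other's partner RNA, so the 0 does not show that the responses were alike. S300001633 and S300001699, raised in the other duals, stood at 63.9 ± 44.6 and 157 ± 94.4 CPM in the dual with P. amylolyticus (n = 3), and the test among duals gave adjusted p = 0.000123 and 2.56e-05. Without dual S. rhizophila 1 the count among duals was 53, and without group weights it was 571.

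In the dual biofilm with P. amylolyticus, 260 X. retroflexus genes changed against single, each by at least 2-fold: 137 fell and the others rose (limma). S300003737, on contig 110 at 258996 to 261476 (plus strand), was 5.39-fold higher, at 5586 ± 1701 against 1018 ± 329 CPM (n = 3 each; log2 2.43 ± 0.37, adjusted p = 9.86e-06). S300003992, on contig 117 at 21084 to 21308 (plus strand), stood at 312 ± 74.2 CPM (n = 3). Its limma log2 fold change was 4.99 ± 0.73 (SE, adjusted p = 5.39e-06). It had 163 read equivalents over the dual group against 1 over the single group. That is a ratio of 70.1 (95% exact counting interval 12.4 to 2786, which leaves out the spread between replicates). S300000238, on contig 15 at 17892 to 18851 (plus strand), fell from 35102 ± 11507 to 1954 ± 394 CPM (log2 -4.11 ± 0.34, adjusted p = 1.31e-11). S300003510, on contig 110 at 1644 to 2072 (minus strand), had 1011 ± 428 CPM in single and a value of 0 in each of the 3 dual libraries, at least 170-fold lower against a floor of 3 reads over the group (adjusted p = 1.21e-08). In the 4-species biofilm S300003737 stood at 1130 ± 124 CPM (n = 5). The gene count was 170 without single 2, 128 without single 3 and 168 without dual P. amylolyticus 1.

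Among runs, the contig 36 run at 18164 to 22871 (5 genes, minus strand) fell in the dual with P. amylolyticus by a mean log2 of -2.69, with 3 members called lower (camera adjusted p = 0.000181). The contig 16 run at 71778 to 77637 fell by -2.82, with 4 of 5 members called lower (adjusted p = 0.000278). Both held with an estimated correlation (adjusted p = 0.0221 each). The contig 106 run at 142049 to 147037 (7 genes) fell by -0.90 (adjusted p = 0.0369), and did not hold (adjusted p = 0.372 with an estimated correlation). The fry test asks whether a run's genes changed at all, not whether they changed more than other genes. It called 1, 0 and 6 of the 17 runs against single for dual S. rhizophila, dual M. oxydans and dual P. amylolyticus, where camera called 1, 1 and 3. For the contig 16 run it gave adjusted p = 0.0350, 0.148 and 0.000294 in these duals. In the 4-species biofilm fry called 12 runs against single and 10, 10 and 6 against the 3 duals, where camera called 2, 1, 2 and 2, and 0 with an estimated correlation.

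In the 4-species biofilm against single, 972 of 2570 genes changed (514 rose, 458 fell; limma), 937 of them by at least 2-fold. Without group weights the count was 825, below those against the duals with S. rhizophila (1272) and M. oxydans (910). S300000238 fell from 35102 ± 11507 CPM in single (n = 3) to 45.5 ± 9.64 CPM (n = 5), a log2 fold change of -9.49 ± 0.29 (adjusted p = 2.39e-27). S300003719, on contig 110 at 232402 to 232719 (minus strand), fell from 16793 ± 3508 to 116 ± 27.3 CPM (log2 -7.20 ± 0.26, adjusted p = 9.10e-25). S300002352, on contig 67 at 38704 to 41592 (minus strand), rose from 203 ± 99.5 to 3068 ± 423 CPM (15-fold, adjusted p = 3.49e-07). S300003992 stood at 319 ± 19.0 CPM, a limma log2 fold change of 5.01 ± 0.67 (adjusted p = 6.14e-08). It had 595 read equivalents against 1 in single, a ratio of 68.7 (95% exact counting interval 12.3 to 2718). Without single 3 the count was 623, with 285 that rose and 338 that fell, and with 10 read equivalents required in every library 124 rose and 151 fell, so the balance of rises and falls is not settled.

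**Figure D2:**
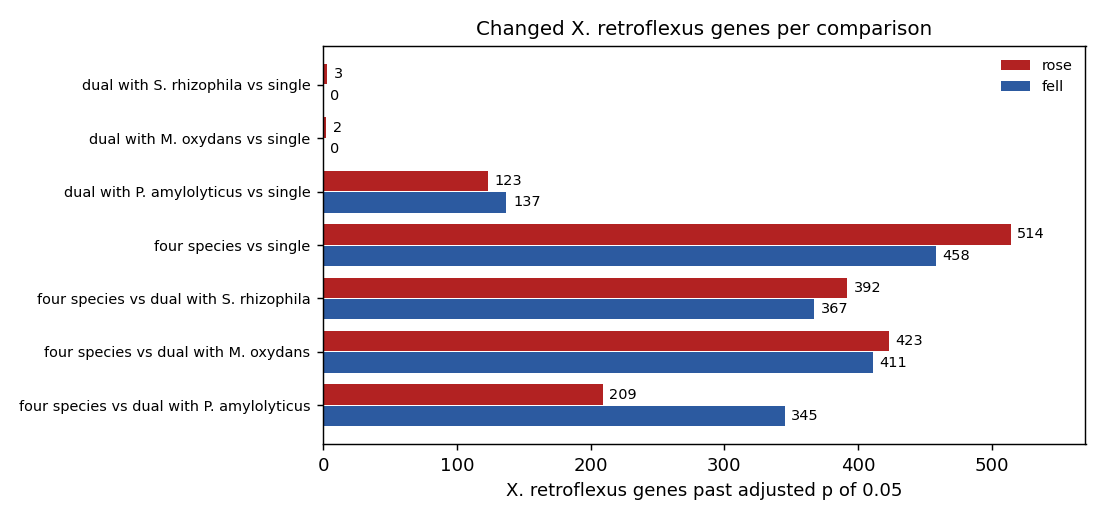
Number of X. retroflexus genes past an adjusted p of 0.05 (horizontal axis) that rose (red) or fell (blue) in each comparison with single and of the 4-species biofilm with each dual. The 4-species comparisons hold 554 to 972 genes each, against 3, 2 and 260 for the duals against single.

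The genes with most signal in the duals with S. rhizophila and M. oxydans were lower in the 4-species biofilm. Of the 50 X. retroflexus genes with the highest level in the duals with S. rhizophila and M. oxydans, 49 fell and 0 rose in the 4-species biofilm against single, with a median log2 fold change of -4.23 (limma). With median-of-ratios scaling 46 fell and 0 rose, with quantile normalization 43 fell and 2 rose, and with the filter of 10 read equivalents in every library 43 of the 48 genes left fell and 1 rose. These 50 genes held 6.45 to 7.43% of X. retroflexus coverage in the 4-species libraries (n = 5), 33.0 to 35.5% in the dual with P. amylolyticus (n = 3) and 39.5 to 62.2% in the other 9 libraries. In the dual with P. amylolyticus 15 of the 50 fell and 1 rose. Each library's own 50 highest genes, which may differ from this set, held 21.9 to 26.9% in the 4-species libraries. They held 36.4 to 39.7% in the dual with P. amylolyticus and 42.3 to 63.0% in the other 9 libraries, a smaller gap. The 4-species libraries also stood apart in breadth and spread: at a matched depth of 69806 read equivalents (the lowest library once each gene was rounded to a whole number), 3681 to 3794 X. retroflexus genes were detected in them and 1993 to 3217 in the others, and replicate Spearman correlations were 0.931 to 0.959 against 0.675 to 0.781. Median-of-ratios scaling moved the median log2 fold change of all genes against single from 0.35 to 0.62 and the split to 666 genes that rose and 387 that fell, and moved the medians of the 4-species comparisons with the duals by 0.24 to 0.29.

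**Figure D3:**
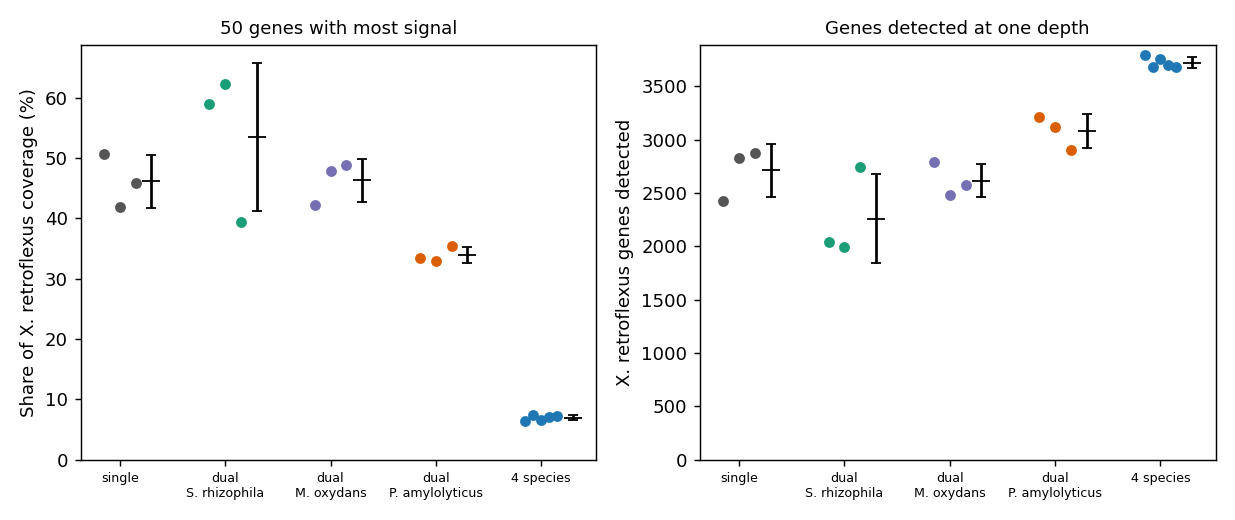
Left, share of X. retroflexus coverage (%) held by the 50 genes with most signal in the duals with S. rhizophila and M. oxydans; right, number of X. retroflexus genes detected after thinning to 69806 read equivalents. Points are libraries and bars the mean ± SD; the 5 4-species libraries lie at 6.45 to 7.43% and 3681 to 3794 genes.

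Many genes changed in both the dual with P. amylolyticus and the 4-species biofilm. Of the genes called against single in both, 219 moved the same way (97 rose, 122 fell) and 5 moved apart. Independent lists of these sizes would share 49.0. The covariance of the log2 fold changes was 1.63, against 0.401 on average in simulated groups with no effect against the same single libraries, and Pearson's r across genes, which are not independent replicates, was 0.65 against 0.71. The 3 single libraries are too few to split, so part of the excess of 219 over 49.0 may come from the shared controls. Of the 219 genes, 51 also differed between the 4-species biofilm and this dual, 40 lying further from single in the 4-species biofilm and 11 nearer. For the runs at contig 106, 142049 to 147037 (mean log2 -2.75, adjusted p = 0.00270) and contig 16, 71778 to 77637 (mean log2 -2.56, adjusted p = 0.00823), both lower in the 4-species biofilm than in single, the median log2 fold changes were -1.19 (3 of 7 members called lower) and -2.58 (4 of 5). Both calls were lost with an estimated correlation (adjusted p = 0.190 and 0.163).

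Against the dual with S. rhizophila, 759 genes changed in the 4-species biofilm (392 rose, 367 fell; limma), and with median-of-ratios scaling 527 rose and 337 fell. S300000616, on contig 19 at 6326 to 6955 (minus strand), was 10.3-fold higher, at 2456 ± 302 (n = 5) against 288 ± 181 CPM (n = 3; adjusted p = 2.41e-05). S300001272, on contig 33 at 17946 to 21188 (minus strand), was 9.53-fold higher (2097 ± 252 against 299 ± 220 CPM, adjusted p = 5.76e-05). S300000238 and S300003719 fell by 9.69 ± 0.37 and 7.50 ± 0.35 on the log2 scale (adjusted p = 1.00e-23 and 1.12e-20). The count was 350 without dual S. rhizophila 1 (62 rose, 288 fell) and 478 without the library labelled dual S. rhizophila 2 (161 rose, 317 fell). It was 460 without both libraries whose partner RNA went against the label (152 rose, 308 fell) and 1272 without group weights (826 rose, 446 fell). The contig 106 run at 142049 to 147037 fell by a mean log2 of -3.12 (median -2.70, 5 of 7 members called lower; camera adjusted p = 0.000468), a call lost with an estimated correlation (adjusted p = 0.244). The run count was 2 without dual S. rhizophila 1 and 2 without the library labelled dual S. rhizophila 2.

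Against the dual with M. oxydans, 834 genes changed (423 rose, 411 fell; limma), and with median-of-ratios scaling 609 rose and 355 fell. With 10 read equivalents required in every library 113 rose and 156 fell, so the balance is not settled here either. S300001023, on contig 27 at 27638 to 27853 (minus strand), was higher, at 739 ± 131 (n = 5) against 14.7 ± 25.4 CPM (n = 3; log2 5.72 ± 0.89, adjusted p = 2.02e-06). Its level was 0 in 2 of the 3 dual libraries, so the size of this change is uncertain: log2 4.27 with a pseudocount of 2 read equivalents and 6.63 without dual M. oxydans 1. S300003992 was higher by a limma log2 fold change of 5.13 ± 0.77 (adjusted p = 9.69e-07). It had 595 read equivalents against 1, a ratio of 78.5 (95% exact counting interval 14 to 3104). S300000238 and S300003719 changed by -9.45 ± 0.31 and -7.30 ± 0.29 on the log2 scale (adjusted p = 4.92e-26 and 1.70e-23). The runs at contig 106, 142049 to 147037, and contig 36, 18164 to 22871, fell by mean log2 values of -2.65 and -2.22 (medians -1.71 and -1.95, with 3 of 7 and 4 of 5 members called lower; camera adjusted p = 0.00441 and 0.00686), and neither held with an estimated correlation (adjusted p = 0.192 for both).

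Against the dual with P. amylolyticus, 554 genes changed (209 rose, 345 fell; limma), and with median-of-ratios scaling 340 rose and 299 fell. S300000369, on contig 16 at 98730 to 98867 (plus strand), was 8.61-fold higher, at 1806 ± 483 (n = 5) against 202 ± 28.6 CPM (n = 3; adjusted p = 8.22e-07). S300002461, on contig 70 at 114251 to 114682 (minus strand), was 4.93-fold higher (1779 ± 244 against 378 ± 139 CPM, adjusted p = 3.25e-06). S300004101, on contig 129 at 73583 to 73987 (minus strand), fell from 35886 ± 11366 to 398 ± 58.7 CPM (log2 -6.46 ± 0.25, adjusted p = 2.91e-23), and S300002985, on contig 90 at 2586 to 4829 (minus strand), fell from 10933 ± 1796 to 328 ± 41.3 CPM (log2 -5.04 ± 0.23, adjusted p = 3.47e-21). Of the 50 genes with most signal, 41 fell in this comparison too. The contig 106 runs at 142049 to 147037 and 285749 to 289818 fell by mean log2 values of -1.86 and -1.40 (medians -0.58 and -1.48, with 3 of 7 and 4 of 6 members called lower; camera adjusted p = 0.0243 each), and neither held with an estimated correlation (adjusted p = 0.358 and 0.349). Without dual P. amylolyticus 1 the run count was 0.

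**Figure D4:**
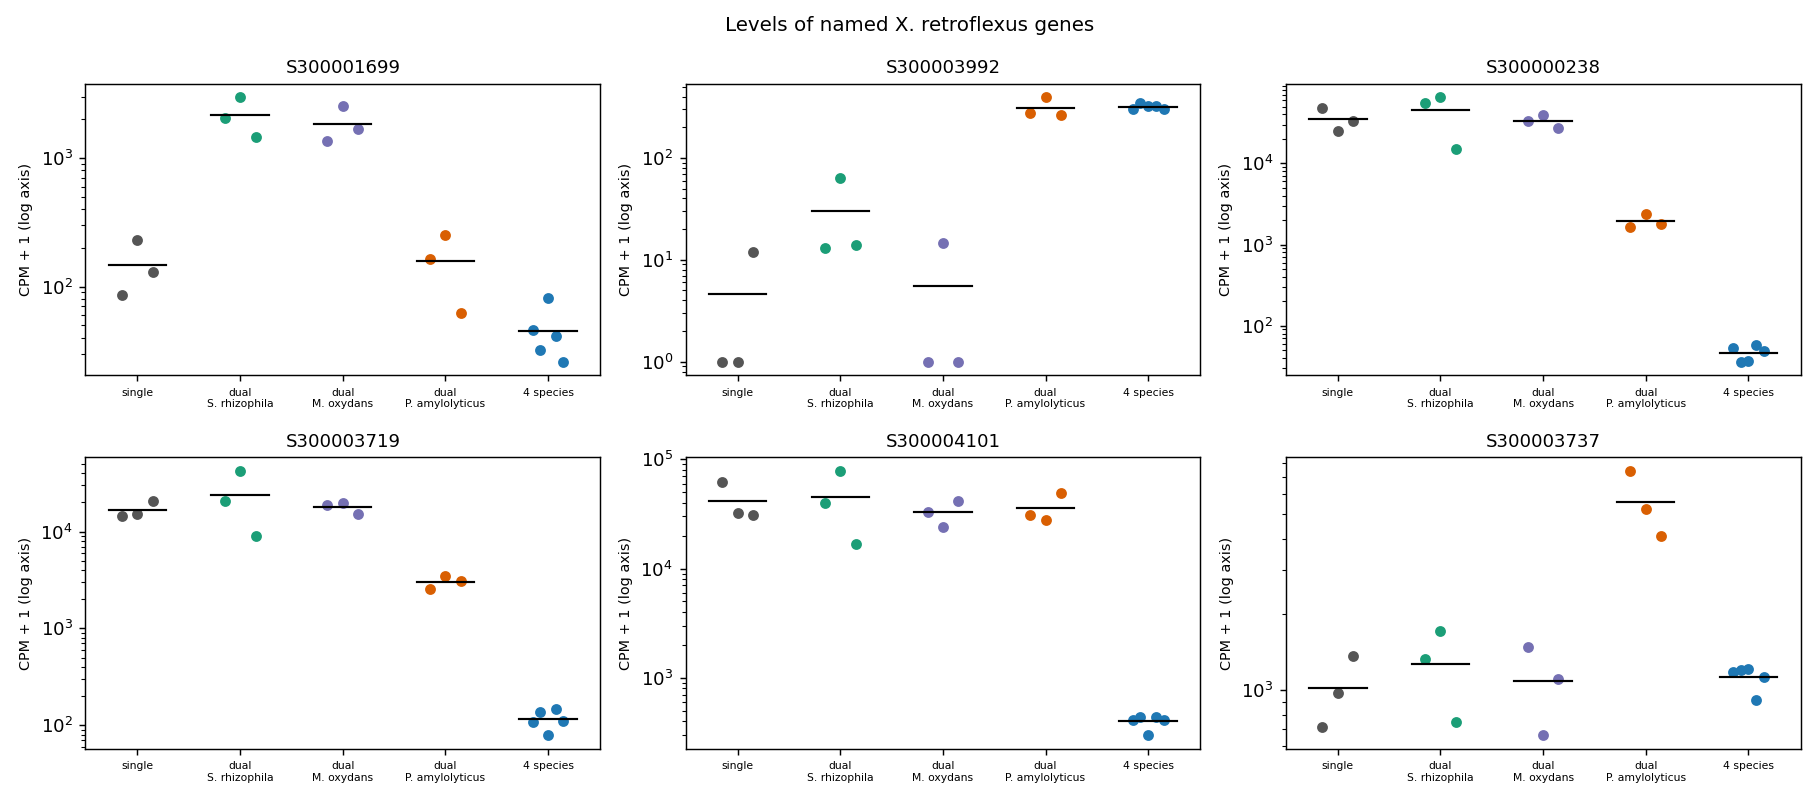
Levels of 6 named X. retroflexus genes as CPM + 1 on a log axis, by group; points are libraries and lines group means. S300001699 is highest in the duals with S. rhizophila and M. oxydans, S300003992 in the 2 groups with P. amylolyticus, S300003737 in the dual with P. amylolyticus, and S300000238, S300003719 and S300004101 are lowest in the 4-species group.

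The 4-species response departed from the sum of the 3 dual responses on the log2 scale for 154 genes, 25 above the sum and 129 below it (limma; 465 at an unadjusted p under 0.05). The median over all 2570 genes lay the other way, at 0.53 above the sum. S300004101 lay at -6.13 from the sum (adjusted p = 4.00e-09), S300002985 at -5.83 (adjusted p = 4.00e-09) and S300000238 at -5.54 (adjusted p = 5.01e-08). S300001699 and S300001633, raised in the duals with S. rhizophila and M. oxydans, lay at -9.25 each (adjusted p = 2.89e-06 and 5.91e-05) and stood at 44.3 ± 21.8 and 20.3 ± 5.67 CPM in the 4-species biofilm (n = 5). S300000369 lay above the sum at 4.71 (adjusted p = 0.00510). The count was 86 without single 2 and 97 without both libraries whose partner RNA went against the label.

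In P. amylolyticus itself, 855 of 2948 genes differed between the 4-species biofilm (n = 5) and its dual with X. retroflexus (n = 3), 309 higher and 546 lower (limma). S700003923, on contig 147 at 28135 to 28998 (minus strand), was 8.48-fold higher (1579 ± 241 against 179 ± 47.1 CPM of P. amylolyticus, adjusted p = 4.88e-08). S700000405, on contig 9 at 25010 to 26479 (plus strand), fell from 7073 ± 1059 to 56.5 ± 12.6 CPM (log2 -6.92 ± 0.28, adjusted p = 4.74e-17). Of its 50 genes highest in the dual biofilm, 36 fell and 1 rose, with a median log2 fold change of -2.65; the ranking used the dual libraries of the same test. The count was 474 without dual P. amylolyticus 1 and 456 without dual P. amylolyticus 3.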

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

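Chosen after the result was seen were the tests on exchanged labels, spill-over, growth of the partner, library preparation, shared controls and reads placed on the wrong species. The abundance trend with separate controls was also chosen then. The tests of depth, of compression, of the abundance trend with shared controls and of other splits were written beforehand.

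The library labelled dual S. rhizophila 2 lacked S. rhizophila RNA above the single libraries and held 0.434% M. oxydans RNA, while the library labelled dual M. oxydans 2 held 12.2% S. rhizophila RNA and 0.00216% M. oxydans RNA. Both partners are out of place in both directions, which is what an exchange of the labels would give, and this is a candidate explanation. Spill-over of reads would add foreign RNA but leave a library's own M. oxydans RNA near the 0.511 and 0.623% of the other dual M. oxydans libraries, and 0.00216% argues against it; a partner that failed to grow would not bring 0.434% M. oxydans. In a separate test among the duals, the grouping with these 2 libraries exchanged called 229 genes, the most of 100 groupings, against 125 with the labels as given. Another grouping against the labels called 169. The groupings with the highest counts all kept the P. amylolyticus duals together, so few of the 100 bear on this exchange. No biological explanation other than growth of the partner was tested.

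Of the 50 genes with most signal in the duals with S. rhizophila and M. oxydans, 49 fell in 4-species against single (43 to 46 under other scalings). They held at most 7.43% of X. retroflexus coverage there, where each library's own 50 highest genes held 21.9 to 26.9%. A difference in depth is argued against, since 48 of the 50 still fell after every library was thinned to 1 depth. Compression of high values keeps rank order, but over the 800 genes with most signal the Spearman correlation of 4-species with single levels was 0.404 (0.368 to 0.420 with 1 library left out), against 0.817 and 0.868 for the duals with S. rhizophila and M. oxydans. A batch or preparation held by the 4-species libraries alone cannot be told apart from the community, since no label gives a batch. The presence of all 4 species remains open as a biological explanation.

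The responses of the dual with P. amylolyticus and the 4-species biofilm shared 97 genes that rose and 122 that fell, with a covariance of 1.63. Controls that share no library were also used, with 4-species minus single as the other comparison. The covariance was 1.22 for this dual minus dual M. oxydans (1.17 to 1.27 with 1 library left out). It was 1.64 for this dual minus dual S. rhizophila (1.37 to 1.93). Shared single libraries alone would give values near 0, so these values argue against them as the whole cause. Dual S. rhizophila minus dual M. oxydans gave -0.422 (-0.712 to -0.158), by construction the first value less the second, so it is no independent benchmark. With the trend in abundance removed the covariance was 1.22 with shared controls, above the highest value of 0.447 in the simulated groups with no effect. With the separate controls it was 0.615 (0.573 to 0.647) and 0.730 (0.621 to 0.828). That trend is therefore argued against as the whole cause. Dual S. rhizophila minus dual M. oxydans gave -0.115 (-0.213 to -0.00592), again no independent benchmark. P. amylolyticus reads placed on X. retroflexus genes would raise those genes, so they do not directly account for the 122 that fell. Independent lists give 24.4 shared falls, a value that leaves out the shared single libraries. Levels are relative to the X. retroflexus total, so reads added to some genes would lower others. The falls therefore cannot decide about misplaced reads. For the 97 that rose they stay open, since the excess in dual P. amylolyticus 2 (1.04 of that in replicates 1 and 3, where such reads would give 0.374) rests on 1 library. The presence of P. amylolyticus is open and untested. A batch or preparation held by its dual and the 4-species libraries cannot be told apart from it, since no label gives a batch. Mean totals were 25.4 (this dual) and 24.3 Mb (4-species), against 4.16 to 8.86 Mb in the other groups. These totals include P. amylolyticus coverage, which the tests left out. Mean X. retroflexus read equivalents were 166991 in this dual and 239971 in 4-species. They were 181712 in dual S. rhizophila, 99614 in dual M. oxydans and 87577 in single, so this dual did not stand apart in X. retroflexus depth. Thinned to equal X. retroflexus depth, the comparisons of this dual and of 4-species with single gave 262 and 806 genes. The shared genes were not recounted, so depth stays open.

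Other splits of the same libraries bear on the gene counts. For the 4-species biofilm against single, 1 of 56 splits reached the real 972, the real one, and the highest other gave 14. The values were 1 of 56 against dual S. rhizophila (759, highest other 73), 1 of 56 against dual M. oxydans (834, highest other 16), 1 of 56 against dual P. amylolyticus (554, highest other 24) and 1 of 56 for P. amylolyticus genes (855, highest other 1). Chance is argued against for these and for the 125 genes among duals (3 of 100 drawn, highest other 229, the exchanged grouping). The other larger split, with 169, also kept the P. amylolyticus duals together, so these draws do not separate the duals with S. rhizophila and M. oxydans. For the 154 genes off the sum of dual responses, 1 of 100 drawn reached the count (highest other 2). Those draws exchanged labels over all 5 groups, which removes every group difference. They therefore cannot decide whether the dual responses add up. The duals against single have 10 splits each, too few for a share under 0.05: real 3, 2 and 260, highest other 1, 0 and 0, each reached by 1 split.

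For runs, chance is not excluded in the 4-species comparisons: 12 of 56 splits gave as many as the 2 against single (highest other 4), 47 as many as the 1 against dual S. rhizophila (highest other 3), 14 as many as the 2 against dual M. oxydans (highest other 3) and 4 as many as the 2 against dual P. amylolyticus (highest other 2). The 10 splits of the duals against single are too few to tell: real 1, 1 and 3 runs, highest other 3, 1 and 2, reached by 7, 4 and 1 splits.

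The response differed among the 3 duals for 125 genes, and of the named genes for S300001633 (adjusted p = 0.000123), S300001699 (2.56e-05), S300003992 (0.00469), S300003737 (0.000942), S300000238 (1.72e-10), S300003510 (3.04e-08) and S300003719 (4.54e-06), all by limma. One library lay far from the others of the 4-species group for 2 of 25 measures, where chance gives about 1 in 20: for S300003737 the gap was 0.711 of the range (916 CPM in 4-species 4, 1130 to 1217 in the others), and for S300004101 0.787 (296 CPM in 4-species 3, 409 to 439 in the others).

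Signal also lay in data outside the comparisons. P. amylolyticus genes held 1.11, 0.869 and 0.879% of coverage in single 1, 2 and 3, in 402 to 505 genes, above the 0.00877 to 0.0779% in the libraries labelled dual S. rhizophila and dual M. oxydans. The contigs that resemble a sequencing control held 1.2 to 8.96% of all coverage, the most in dual S. rhizophila 3.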

How the results depend on the processing

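Alternatives without the 2 libraries whose partner RNA went against their label, without group weights, with weights per library, with a pseudocount of 2, with quantile normalization, with the control-like contig, and leaving out libraries for runs, were chosen after seeing the data. No named gene or run reversed, but the balance of rises and falls did. Of 208 recomputed gene counts, 39 moved by more than 1.5 times. Named genes kept their direction in 507 of 507 settings and their call in 490. Settings in which a gene did not pass the filter are not among the 507. Share differences kept their direction in 180 of 180 settings and passed correction in none, which these group sizes did not allow. Named runs kept their call in 112 of 134. Unless a cause is given, the cause was not tested. The planned second count model was not run, since the values are not counts, nor were functional lists or tests of S. rhizophila and M. oxydans genes. Few 2-fold changes were recovered on simulated data for the duals with S. rhizophila and M. oxydans, where replicates spread widely (median SD of log2 values 1.23 and 0.943); depth was not separated from spread.

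For 4-species against single, 514 rose and 458 fell, but 285 and 338 without single 3. Against dual S. rhizophila, 392 rose and 367 fell, but 62 and 288 without its library 1. Against dual P. amylolyticus, 209 rose and 345 fell, but 340 and 299 with median-of-ratios scaling. Against dual M. oxydans, 423 rose and 411 fell. With the strictest filter falls outnumbered rises in all 4: 124 and 151 against single, and 94 and 140, 113 and 156, 108 and 146 against the 3 duals.

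Requiring 10 read equivalents in every library left 414 genes, and the counts were 0 for the duals with S. rhizophila and M. oxydans, 121 for the dual with P. amylolyticus, 275 for 4-species against single, 234, 269 and 254 against the 3 duals in that order, 53 among duals and 520 for P. amylolyticus genes. Fewer genes and a new scaling both enter: for 4-species against single, 254 of the 972 genes lay among the 414, only 197 of the 275 were shared with the 972, and the median log2 fold change of the 414 went from -0.90 to -0.13. For the dual with M. oxydans the count was 1 with median-of-ratios scaling, without a filter, with only the libraries compared and without group weights, and 0 with the contig rule at a fraction of 0.5, which gave 1 for the dual with S. rhizophila. Without group weights counts were 38 for the dual with S. rhizophila, 1272 for 4-species against it and 571 among duals. Weights per library gave 4, 845 and 172 for these, and no count beyond 1.5 times. The form of weights was chosen with these counts in view. Without both doubted libraries they were 460 for 4-species against dual S. rhizophila and 97 off the sum of dual responses.

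Same-numbered libraries did not deviate together (correlations -0.062 to 0.036 over 30 pairs; 1 of 17 libraries correlated best with its own number), so the numbers do not pair them. The replicate block gave 6 genes for the dual with S. rhizophila and 241 among duals, and moved no other count by over 1.5 times.

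Leaving out 1 library gave 0 to 24 genes for the dual with S. rhizophila, 0 to 3 for that with M. oxydans, 128 to 227 for that with P. amylolyticus, 623 to 1007 for 4-species against single, 350 to 804, 605 to 884 and 394 to 626 against the 3 duals in the same order, 53 to 153 among duals, 86 to 199 off the sum and 456 to 861 for P. amylolyticus genes. For 4-species minus dual, S. rhizophila shares differed by -7.80 to -2.60 points, M. oxydans by -0.544 to -0.234, P. amylolyticus by -23.6 to -12.3 and X. retroflexus against dual P. amylolyticus by 9.67 to 20.8, the extremes without 1 dual library. Run counts, for the 3 duals against single in that order, then 4-species against single and against these duals, were 0 to 2, 0 to 1, 2 to 4, 2 to 3, 1 to 2, 2 to 2 and 0 to 2. With an estimated correlation they were 0 except the 2 for dual P. amylolyticus. With gaps under 100 bp they were 2, 3 and 6 for the duals and 4 for 4-species against single. Without both doubted libraries they were 2 for the dual with S. rhizophila, 0 for that with M. oxydans and 2 for 4-species against dual S. rhizophila.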

Other observations

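The test of neighbouring genes was written before its result was seen, and the P. amylolyticus gene was chosen after. Neighbouring X. retroflexus genes changed together in the 4-species biofilm. Across 632 adjacent pairs on 1 strand less than 50 bp apart, the log2 fold changes against single had a Spearman correlation of 0.369, against 0.133 for 631 adjacent pairs on 1 strand farther apart and 0.165 for 519 adjacent pairs on opposite strands. The hypothesis was that close neighbours share transcripts. The difference between close and opposite-strand pairs was 0.204, beyond the 95th percentile of 10000 reassignments of pairs to classes (0.0944, one-sided permutation p = 0.0003). Successive pairs share a gene and are not independent, so this p may be too small. The higher correlation of close pairs is what shared transcripts would give, although reads that cover the ends of both genes may add to it. Only 4-species against single was examined, so the pattern is not shown to be particular to this biofilm.

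The P. amylolyticus gene with most signal, S700000176, on contig 5 at 201 to 476 (plus strand), was singled out after its values were seen. It held 16.8 to 34.1% of P. amylolyticus coverage in the 4-species libraries and 4.99 to 10.0% in its dual, and the difference did not pass the test (log2 1.57 ± 0.69, limma adjusted p = 0.141). Its contig has an assembly coverage of 2320, against a median of 63.5 over P. amylolyticus contigs.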
